A study of Homo sapiens with 10 samples.

How the data were processed

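The values are linear MAS5 signal intensities of Affymetrix U133 Plus 2.0 arrays, 1 per probe set, made by the authors with GCOS 1.4 and MAS5 per the labels, and scaled before they were deposited so that the 2% trimmed mean of each array is 500. The labels mention a log2 transformation, but the deposited values are positive, linear and of wide range, so log2 was taken here. Labels also give the siRNA, stimuli, doses and times used above, while the siRNA sequence is not given. All 10 columns were mapped to a sample, and the pairing of ID1 siRNA with control siRNA follows line and stimulus in the labels. Of 54675 probe sets, 62 controls, 1801 with several gene symbols and 11777 without a gene in the annotation were set aside. The remaining 41097 carried 1 symbol each, and 41043 of them were matched by Entrez identifier. Some genes without a usable annotation were not analysed here.

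For each of 19775 genes the probe set with the highest mean log2 signal was kept, and 12515 genes with a mean at or above the median of all probe sets (log2 6.06, signal 66.7) were tested. Limma 3.58.1 in R 4.3.3 was used with moderated tests, an intensity trend and Benjamini-Hochberg adjustment, and a call is an adjusted p under 0.05. Line and condition were the terms of a fit to all 10 arrays, which has 4 residual degrees of freedom and gave 7 contrasts. A fit to the 8 stimulated arrays had the 4 matched pairs as blocks and an ID1 siRNA term within each line, with 2 residual degrees of freedom, and gave the effect within A549, within H1650 and their difference. Fold changes per pair of arrays were counted at 2-fold without a test. Where a probe set was dim in the lower group, an at least fold compares the bright group with the higher of its value and the array's median, and no fold is printed if that is under 1.

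The 25 gene lists, fixed with the design before the data were examined, were the ID family and bHLH partners, ID1 candidates from work on lung cancer lines, epithelial and mesenchymal markers, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors, p53 targets, EGF and ERK response, nicotinic receptor subunits, TGF-beta and BMP targets, interferon response, NF-kB and inflammatory cytokines, invasion and matrix proteases, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and integrated stress response, NRF2 targets, stem cell factors, lung epithelial lineage, markers of other cell types, ribosomal proteins, oxidative phosphorylation, stathmins and tubulins, and the BCL2 family. Camera in limma tested them with a preset correlation between genes of 0.01, adjusted over 175 combinations of list and contrast, and camera with an estimated correlation was run beside it. The 75 combinations within and between lines were added after the first results, and adjusted as a family of their own. For single pairs the list median was placed among 10000 random lists matched on mean signal in 20 bins.

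Genes are named by a rule set before the data were examined: up to 10 per direction and contrast with the largest fold change among those that passed and moved the same way in every matched pair, or, where too few passed, among those at least 2-fold changed in every pair, given as values only. Within a line, the smaller of the pair's 2 changes, at least 2-fold, set the rank. ID1, list members that passed or were largest, and control probe sets were named as well. The text names a selection of these genes, and that selection was made after the values were seen.

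The tests were repeated, as chosen before the data were examined, with quantile normalization, centring each array on its median, adding 16 to the signal, other filters, the mean of all probe sets, no intensity trend, other blocks, leaving out each array, 1.5-fold, and fry in limma for lists. Camera within lines, camera without the A549 array labelled unstimulated control and 2-fold genes without the A549 EGF control were added later. Other probe sets of ID1 could not be compared because there was 1. In a self-test, 200 of 12515 simulated genes were changed, and the share recovered at 2-fold was 68.7% for the mean ID1 siRNA effect, 80.6% within A549, 79.1% within H1650 and 59.7% for the difference between lines. At 1.5-fold these shares were 29.9%, 50.7%, 49.3% and 22.4%. For ID1 siRNA under nicotine 44.8% were recovered at 2-fold and 2.99% at 1.5-fold, and for nicotine against no stimulus 53.7% and 2.99%. False calls made up 5.00% to 8.06% of calls, and 0 of 25 unchanged lists were called. The simulated genes varied independently, so the lists in this test cannot show what correlation between genes does to camera calls.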

Results

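Transcript levels were measured on 10 oligonucleotide arrays in a pair of human non-small cell lung carcinoma lines, A549 and H1650. The series concerns genes downstream of ID1, a helix-loop-helix protein that binds basic helix-loop-helix transcription factors and keeps them off DNA. Each line had 5 arrays, 1 per condition: control siRNA without a stimulus, control siRNA with nicotine, ID1 siRNA with nicotine, control siRNA with EGF, and ID1 siRNA with EGF. Cells had been serum starved for 48 h and stimulated for 18 h with 1 µM nicotine or 100 ng/ml EGF, the ligand of the epidermal growth factor receptor. Signals were scaled so that the trimmed mean of each array was 500, and the median signal of an array lay between 61.2 and 79.5. There was n = 1 array per line and condition, and nothing in the labels says that arrays came from separate cultures. A gene's own spread therefore measures only how far the 2 lines, or the 2 stimuli within a line, differed in an effect. The moderated tests combine it with the spread of other genes of similar signal, so p-values and errors rest on both. In the fit within lines, the gene's own spread had 2 degrees of freedom, and the part from other genes a median of 6.64. In the fit of line and condition these were 4 and 4.47. Errors beside log2 fold changes are limma standard errors. The estimates rest on 5 conditions per line for A549 against H1650. They rest on 4 matched pairs of arrays for the mean effect and for differences between effects, and on 2 pairs otherwise. A gene's own spread behind each error is that of the whole fit, pooled over both lines. Each gene thus has the same error within A549 and within H1650. For IFI44L, MMP3 and HK2 in A549, CCL2 in H1650, and GREM1, RASD1, SPOCD1 and FOS under the stimuli, the lower group lay below the signal filter, so the sizes of their changes are uncertain.

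ID1, the targeted gene, was lower on all 4 arrays labelled ID1 siRNA than on their matched controls. In H1650 its signal was 881 with ID1 siRNA against 4964 with control siRNA under nicotine, and 1031 against 5121 under EGF. The signal was thus 82.3% and 79.9% lower. In A549 it was 1343 against 3720 under nicotine and 1343 against 3049 under EGF, or 63.9% and 56.0% lower. Unstimulated H1650 controls had an ID1 signal of 5030, close to that of the stimulated controls. The A549 array labelled unstimulated control had 1645, which made the nicotine control 2.26-fold and the EGF control 1.85-fold higher, with no replicate of any of these arrays. ID1 was represented by 1 probe set.

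**Figure D1:**
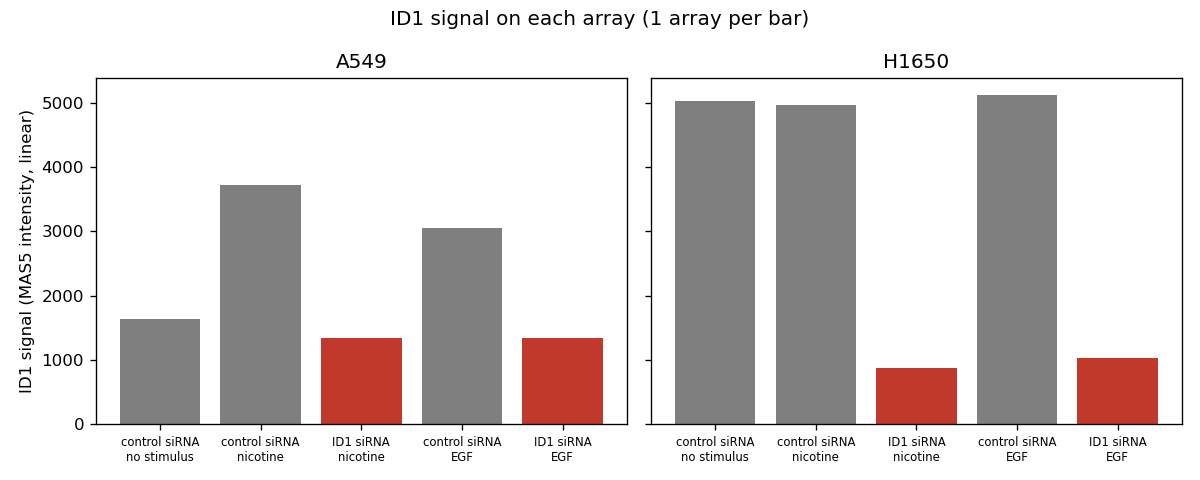
ID1 signal (linear MAS5 units) on each of the 10 arrays, grouped by line, with 1 bar per array (grey control siRNA, red ID1 siRNA) and no error bars because there was 1 array per condition. ID1 siRNA arrays lay between 881 and 1343, and the A549 array labelled unstimulated control, at 1645, lay nearer to them than to the stimulated A549 controls at 3049 and 3720.

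Of the hybridisation spikes, bioB and bioC were brighter with ID1 siRNA in all 4 pairs and cre was not. The spike bioB was 1.44-fold and 1.60-fold brighter on the A549 ID1 siRNA arrays than on their controls, and 1.28-fold and 1.24-fold brighter in H1650, and bioC had signals of 2393 against 1860 and 3067 against 2140 in A549 and 2408 against 1954 and 2518 against 2120 in H1650, whereas cre was at 0.994-fold and 0.785-fold in A549 and 0.993-fold and 1.12-fold in H1650. The 3' to 5' signal ratio of GAPDH, a measure of RNA integrity, was between 0.887 and 0.945 on all arrays, and that of ACTB between 1.23 and 1.52. Array medians over all probe sets, untested ones included, were on average 0.29 higher (log2) with ID1 siRNA in A549 and 0.05 higher in H1650. The tested genes alone had medians of 0.01 with nicotine and 0.08 with EGF in A549, and -0.03 and 0.01 in H1650. Centring on the array median thus moves A549 genes by more than their own median, and small A549 changes depend on the scaling. The A549 array labelled unstimulated control correlated across genes at r = 0.980 and 0.974 with the ID1 siRNA arrays and at 0.973 and 0.969 with the stimulated controls, whereas the H1650 one correlated at 0.974 and 0.972 with the ID1 siRNA arrays and at 0.988 and 0.980 with the controls. Genes are not independent replicates, and these values describe single arrays.

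Among the 25 gene lists, detoxifying enzymes and epithelial markers had the largest median differences between A549 and H1650. All 19 tested targets of NRF2, the transcription factor of the oxidative stress response, were higher in A549, with a median log2 difference of 2.56. Among them GPX2, a glutathione peroxidase, was at least 233-fold higher, the aldehyde dehydrogenase ALDH3A1 at least 269-fold and the aldo-keto reductase AKR1C3 at least 339-fold. Of 19 epithelial markers, 14 were lower in A549 and 3 higher, including CDH3 (P-cadherin), at least 146-fold lower, CLDN7, a tight junction claudin, at least 58.8-fold lower, and RAB25, an epithelial GTPase, at least 54.7-fold lower. Outside the lists, ALDH1A1, a retinal dehydrogenase, was at least 321-fold higher and the matrix protein MGP at least 99.1-fold lower in A549. In all, limma called 7894 of 12515 genes, 3863 higher and 4031 lower in A549. Targets of p53, the damage-response transcription factor, were higher for 14 of 17 and lower for 1, with GDF15, a stress-induced cytokine, at 2.81 ± 0.15. Hypoxia and glycolysis genes were lower for 11 of 16, with HK2, the first enzyme of glycolysis, at -6.27 ± 0.56. Counts were equal when adjusted over the list alone for these 4 lists. Camera adjusted p-values were 1.08e-09 for NRF2 targets, 0.00068 for epithelial markers, 0.00193 for p53 targets and 0.00367 for hypoxia genes, but each had adjusted p = 0.973 with an estimated correlation.

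Within A549, ID1 siRNA was accompanied by higher interferon-induced and inflammatory transcripts and lower cell-cycle transcripts. All 25 tested interferon response genes rose, with a median log2 change of 3.03. IFI44L, an interferon-induced protein, rose by 5.23 ± 0.39, OAS2, an antiviral oligoadenylate synthetase, by 4.31 ± 0.24, IFITM1, a membrane protein that restricts viral entry, by 4.13 ± 0.16, and MX1, an antiviral GTPase, by 3.84 ± 0.11. BST2 (tetherin) was at least 13.9-fold higher and GBP1, a guanylate-binding GTPase, 24.5-fold higher (log2 4.61). Other bright probe sets rose less, by a log2 of 2.09 and 2.35 for OAS2 and of 3.14 and 3.59 for GBP1. In the NF-kB and inflammatory list 14 of 17 genes rose and 0 fell, led by the chemokine CCL20 (2.39 ± 0.14), the cytokine IL6 (2.37 ± 0.15) and TNFAIP3, a feedback inhibitor of NF-kB (2.09 ± 0.19). Limma called 3161 genes in this line, 1733 higher and 1428 lower, ID1 itself at -1.33 ± 0.11.

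Some mesenchymal markers and some invasion and matrix protease genes also rose in A549. Of 16 mesenchymal markers 8 rose and 1 fell: the actin-binding protein TAGLN rose by 2.01 ± 0.28, the fibrillar collagen COL5A1 by 1.62 ± 0.14 and smooth muscle actin ACTA2 by 1.64 ± 0.19, whereas S100A4 fell by 0.47 ± 0.14. Among 17 invasion and matrix protease genes 10 rose, such as the stromelysin MMP3 (2.25 ± 0.41), urokinase PLAU (1.96 ± 0.17), the gelatinase MMP2 (1.78 ± 0.21) and the collagenase MMP1 (1.48 ± 0.19). The 3 that fell were the metalloprotease inhibitors TIMP2 (-0.86 ± 0.13) and TIMP1 (-0.45 ± 0.14) and the sheddase ADAM10. Of 17 p53 targets 12 rose and 1 fell. The death receptor FAS rose by 1.57 ± 0.14, MDM2, the p53 ubiquitin ligase, by 1.00 ± 0.11 and the CDK inhibitor CDKN1A by 0.94 ± 0.11, while RRM2B, a ribonucleotide reductase subunit, fell by 0.53 ± 0.11. In the unfolded protein and integrated stress list 8 of 17 rose, with the lipoprotein receptor VLDLR at 1.90 ± 0.14, the stress transcription factor ATF3 at 1.52 ± 0.16 and the pseudokinase TRIB3 at 1.16 ± 0.14. In the BCL2 family 6 of 14 rose, among them BCL2A1, which opposes apoptosis (0.78 ± 0.21), and BIK, which promotes it (0.76 ± 0.13). In cholesterol synthesis 6 of 13 rose, led by HMGCS1 (0.76 ± 0.12), and FDPS fell by 0.44 ± 0.13. After array-median centring 7 p53 targets rose and 3 fell, and 8 stress genes rose and 3 fell. For the BCL2 family the counts were 1 and 2, and for cholesterol synthesis 2 and 2. The interferon, protease and NF-kB lists then had 25, 10 and 13 rising.

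Replication and mitosis genes fell in A549. Of 22 G1/S and DNA replication genes 12 fell and 0 rose, with the flap endonuclease FEN1 at -0.98 ± 0.14, cyclin CCNE2 at -0.72 ± 0.10 and the replisome subunit GINS2 at -0.69 ± 0.10. Of 21 G2/M genes 15 fell and 0 rose, such as the spindle factor TPX2 (-0.75 ± 0.10) and the mitotic kinase AURKA (-0.66 ± 0.10). NRF2 targets fell for 7 of 19, including ALDH3A1 (-1.15 ± 0.22) and GCLC, an enzyme of glutathione synthesis (-0.85 ± 0.10), while haem oxygenase HMOX1 rose by 0.48 ± 0.12. Oxidative phosphorylation genes fell for 3 of 18 (NDUFA1, a complex I subunit, at -0.73 ± 0.14), stathmins and tubulins for 5 of 13, with TUBB2B up by 1.30 ± 0.24, and ribosomal proteins for 1 of 14 (RPL3, -0.54 ± 0.15). Outside the lists, AQP3, a water and glycerol channel, fell by 1.87 ± 0.17, with other bright probe sets at -0.66 and -0.42, and VAMP3, a vesicle SNARE, by 1.65 ± 0.11. After array-median centring 16 oxidative phosphorylation, 13 ribosomal, 9 tubulin and 14 NRF2 genes fell instead.

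Camera adjusted p-values for the A549 lists were 2.12e-24 for interferon, 1.32e-09 for NF-kB, 8.24e-08 for G1/S, 1.27e-07 for G2/M, 0.000243 for oxidative phosphorylation, 0.000267 for NRF2, 0.000311 for p53 and between 0.00208 and 0.0377 for the other 8 called, which include the ID1 candidate list. With an estimated correlation these 15 lists had adjusted p = 0.535 to 0.684 and were not called. Adjusted over the list alone, 25 interferon, 14 NF-kB, 13 p53, 10 protease, 9 mesenchymal, 8 stress, 7 BCL2 and 6 cholesterol genes rose, and 15 G1/S, 17 G2/M, 9 NRF2, 7 oxidative phosphorylation, 7 tubulin and 0 ribosomal genes fell. The scaling mattered for the small shifts: quantile normalization turned the ribosomal median from -0.34 to 0.01, array-median centring turned the stress median from 0.26 to -0.03, and adjusted p rose above 0.05 for NRF2, oxidative phosphorylation, ribosomal proteins, tubulins and the ID1 candidates under the former and for tubulins and cholesterol under the latter.

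The remaining lists were not called in A549, except that quantile normalization gave TGF-beta and BMP targets and ERK response genes an adjusted p of 0.0166 each by camera. Members that passed included CCN2 (2.55 ± 0.21) and LTBP2 (1.98 ± 0.18), both matrix proteins among 4 of 13 TGF-beta and BMP targets that rose (camera adjusted p = 0.0544), and the growth factor HBEGF (1.57 ± 0.13) and the early-response factor EGR1 (1.55 ± 0.21) among 6 of 19 ERK response genes that rose while 2 fell (0.098). In the ID family and bHLH partners 5 of 11 rose and 1 fell: ID4 rose by 1.90 ± 0.24 and ID3 by 0.66 ± 0.10, and ID2 fell by 1.35 ± 0.17 (0.213). The transmembrane mucin MUC1 (1.41 ± 0.12) was 1 of the 6 epithelial markers of 19 that rose (0.481). HK2 rose by 3.03 ± 0.36, and the hypoxia list had 3 of 16 genes higher and 3 lower, BNIP3, a mitophagy receptor, at -0.88 ± 0.13 (0.874). Stem cell factors rose for 3 of 6 and fell for 1, SOX2 rising by 0.75 ± 0.21 (0.412), and CDKN1A was the 1 of 5 CDK inhibitors to pass (0.658). The 8 nicotinic receptor subunits (0.669), 5 lung lineage genes (0.918) and 4 markers of fibroblast, endothelial or blood cells (0.953) had 0 passing members by limma, with medians of 0.27, 0.12 and -0.17. After array-median centring 3 epithelial markers rose and 6 fell, 6 and 6 ERK response genes, 2 and 2 TGF-beta targets, 4 and 3 ID family genes, and 2 and 7 hypoxia genes. Adjusted over the list alone the counts were 4, 7, 5, 6, 3, 3 and 1 rising for the first 7 of these lists, and 0 for the last 3.

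Within H1650, the interferon and cell-cycle lists moved the other way. Interferon genes fell for 15 of 25 and rose for 0, with a median of -0.87: the RNA sensor RIGI fell by 1.74 ± 0.13, RSAD2 (viperin) by 1.59 ± 0.16, IFI44L by 1.54 ± 0.39 and MX1 by 1.07 ± 0.11. Of 21 G2/M genes 17 rose and 0 fell, with a median of 0.61, including the mitotic kinesin KIF20A (1.04 ± 0.20), survivin BIRC5 (0.91 ± 0.13) and the proliferation marker MKI67 (0.81 ± 0.12). Of 22 G1/S genes 14 rose and 0 fell, led by MCM3, a subunit of the replicative helicase (1.08 ± 0.10), and CDC45 (0.76 ± 0.13). Among 17 p53 targets 5 fell and 1 rose: TP53INP1, an inducer of autophagy and cell death, fell by 1.20 ± 0.18 and MDM2 by 0.51 ± 0.11, RRM2B fell as in A549, and GDF15 rose by 0.54 ± 0.13. Limma called 1540 genes, 706 higher and 834 lower, but only 1, P3H3, without the intensity trend.

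Among single H1650 genes, ID1 fell by 2.40 ± 0.11 (5.29-fold), the cytidine deaminase APOBEC3G by 2.30 ± 0.26 (4.93-fold) and TMEM150C by 2.18 ± 0.26. GALNT7, an enzyme of O-glycosylation, fell by 1.78 ± 0.13. REEP5, a shaper of the endoplasmic reticulum, fell by 1.76 ± 0.11, although a second bright probe set of REEP5 stood at 0.19. PPP2R2D, a regulatory subunit of phosphatase 2A, rose by 2.45 ± 0.20 (5.48-fold), with a second bright probe set at -0.24, and the prolyl hydroxylase P3H3 was at least 1.29-fold higher. In the lists that camera did not call, CCL2 rose by 1.14 ± 0.28, the NF-kB subunit RELB fell by 0.93 ± 0.15, MMP1 fell by 1.46 ± 0.19 and TIMP2 by 1.07 ± 0.13, MMP3 rose by 1.97 ± 0.41, PHGDH, the first enzyme of serine synthesis, rose by 1.07 ± 0.10, and the ERK pathway ligand EREG rose by 1.17 ± 0.17. Camera adjusted p-values were 2.15e-15 for G2/M, 1.11e-10 for G1/S, 1.66e-10 for interferon, 0.0242 for p53 and 0.0284 for the ID1 candidates, and with an estimated correlation adjusted p = 0.535 to 0.607. Adjusted over the list alone, 21 G2/M and 17 G1/S genes rose, 19 interferon and 6 p53 genes fell, and 1 of each of the last 2 lists rose. These 5 directions held under quantile normalization and array-median centring.

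**Figure D2:**
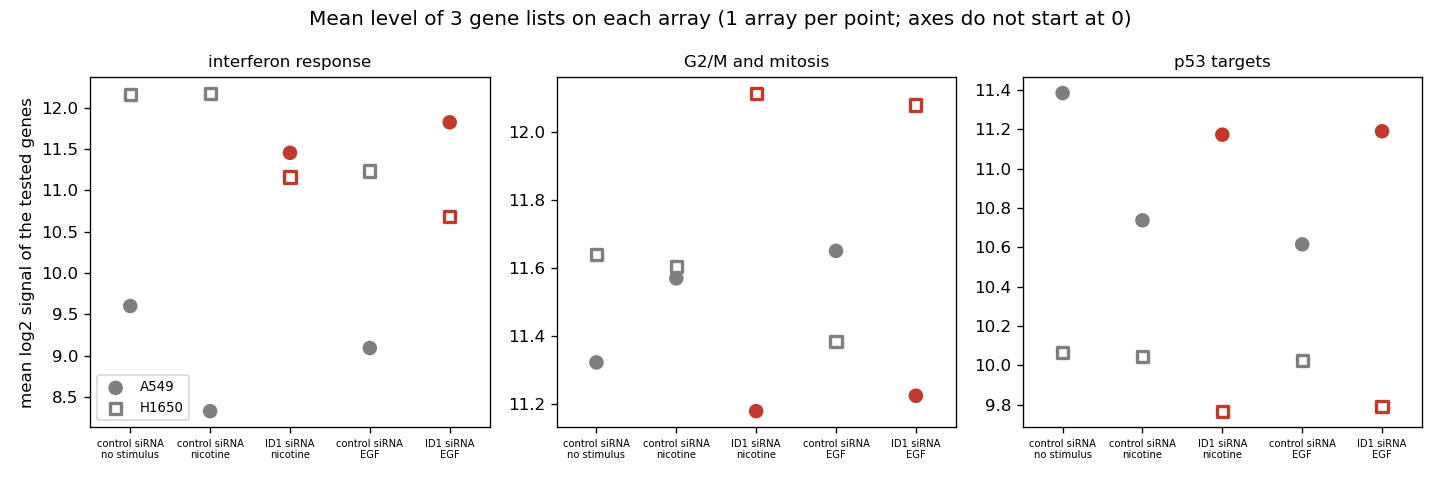
Mean log2 signal of selected gene lists on each of the 10 arrays, 1 point per array with no error bars. Interferon genes averaged 11.45 and 11.82 on the A549 ID1 siRNA arrays against 8.33 and 9.09 on their controls, and 11.16 and 10.69 on the H1650 ID1 siRNA arrays against 12.18 and 11.23.

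The test of the difference between lines bore on which ID1 siRNA effects were larger or opposite in A549. The interferon effect was higher in A549 for 24 of 25 genes, with a median difference of 3.73 and IFI44L at 6.77 ± 0.56. XAF1 and CMPK2, which interferon also induces, differed by 6.16 ± 0.32 and 5.80 ± 0.19. The effect on G2/M genes was lower in A549 for 20 of 21 (BIRC5, -1.32 ± 0.18) and on G1/S genes for 20 of 22 (GINS2, -1.34 ± 0.14). It was higher in A549 for 12 of 17 NF-kB genes (IL6, 2.90 ± 0.22), 10 of 17 p53 targets (MDM2, 1.51 ± 0.15), 8 of 17 proteases (MMP1, 2.94 ± 0.27), 5 of 16 mesenchymal markers (TAGLN, 2.39 ± 0.40), 6 of 19 ERK response genes (EGR1, 1.99 ± 0.30), 5 of 14 BCL2 family genes and 3 of 13 cholesterol genes, with S100A4 (-1.16 ± 0.20) and EREG (-1.07 ± 0.24) the other way. NRF2 targets were lower for 6 of 19, but for 0 under quantile normalization and 11 after centring, oxidative phosphorylation for 1 of 18 and ribosomal proteins for 0 of 14. ID1 itself was lowered less in A549, by a difference of 1.08 ± 0.15 (limma adjusted p = 0.00371).

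Limma called 1490 genes for the difference, 874 higher and 616 lower in A549, but 624 higher and 1821 lower after array-median centring. Adjusted over the list alone, 25 interferon, 13 NF-kB, 12 p53, 10 protease, 8 ERK, 6 mesenchymal, 5 BCL2 and 4 cholesterol genes were higher, and 21 G2/M, 21 G1/S and 7 NRF2 genes lower. Camera adjusted p-values were 6.16e-31 for interferon, 1.83e-19 for G2/M, 2.31e-16 for G1/S, 6.12e-10 for NF-kB, 1.65e-07 for p53 and between 2.66e-05 and 0.0274 for the other 8 lists named here, all with adjusted p = 0.535 to 0.675 with an estimated correlation. Under quantile normalization the oxidative phosphorylation and ribosomal calls were lost, at adjusted p = 0.325 and 0.851, and the stress and TGF-beta lists gained, at 0.0117 and 0.0343. A call rested on 2 pairs per line with the stimuli standing in for replicates.

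**Figure D3:**
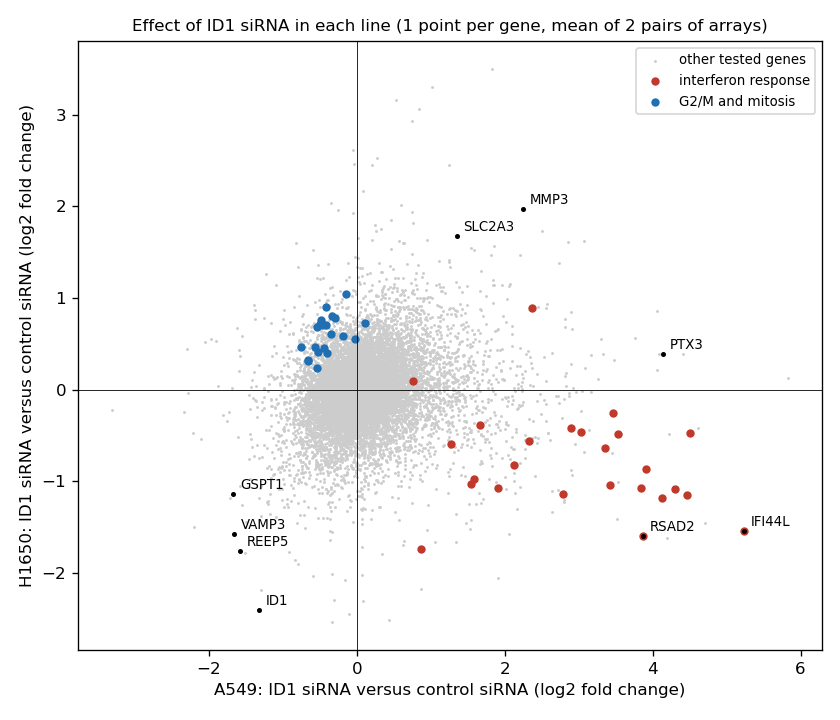
Log2 fold change with ID1 siRNA in H1650 (vertical axis) against A549 (horizontal axis), 1 point per tested gene, each the mean of the nicotine and EGF pair of a line. Interferon genes (red) lie to the right and mostly below 0, with medians of 3.03 in A549 and -0.87 in H1650.

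**Figure D4:**
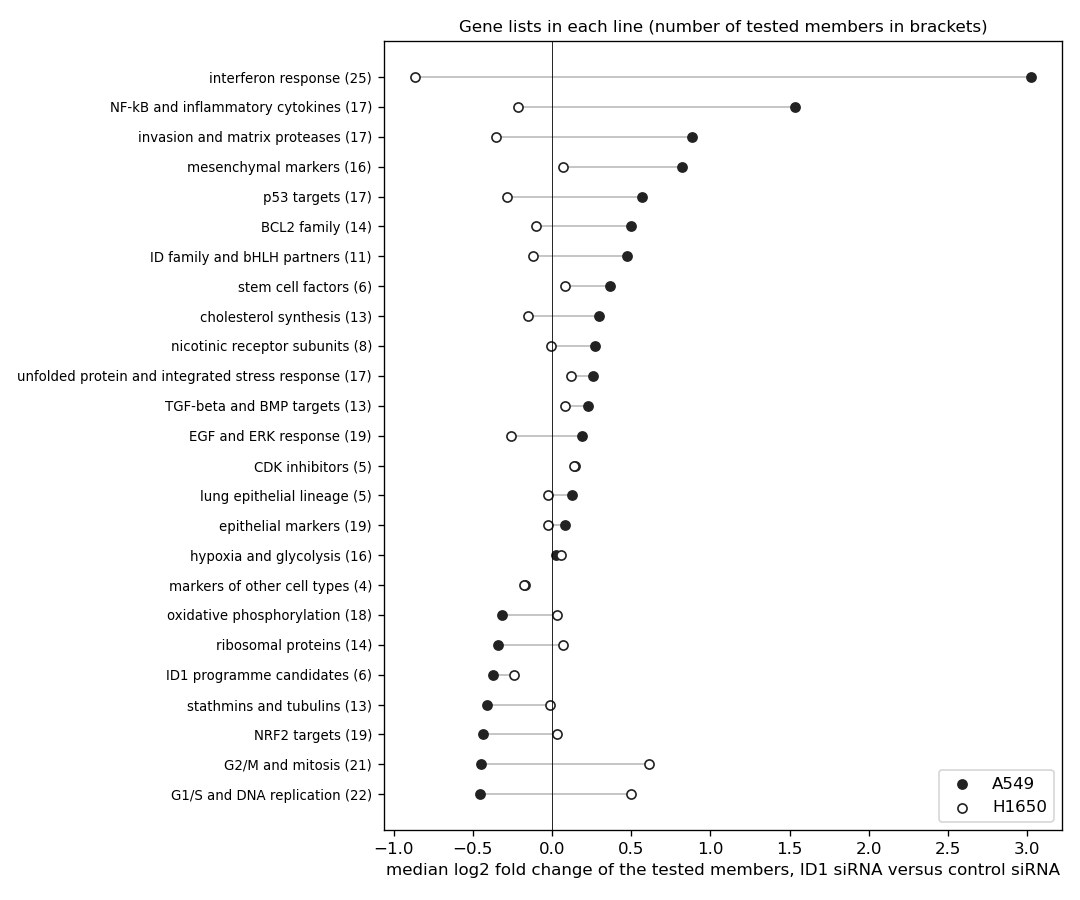
Median log2 fold change with ID1 siRNA of each gene list in A549 and in H1650, 1 point per list and line. G2/M genes lie at -0.45 in A549 and 0.61 in H1650, and interferon genes at 3.03 and -0.87.

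Genes that moved alike in both lines bear on the series' main question, which genes change when ID1 is lowered. A response to the siRNA itself could not be told from ID1 loss for them, as the labels name no second ID1 siRNA and give no sequence. AXL, a receptor tyrosine kinase, fell by 1.47 ± 0.12 over the 4 pairs (limma adjusted p = 0.0130), REEP5 by 1.67 ± 0.22, GALNT7 by 1.65 ± 0.22, VAMP3 by 1.61 ± 0.24, the membrane protein TMEM150C by 1.74 ± 0.28 and ID1 by 1.86 ± 0.32. Among genes that rose, MMP3 stood at 2.11 ± 0.39, the proteoglycan-like MAMDC2 at 1.84 ± 0.33, the glucose transporter SLC2A3 at 1.51 ± 0.18, the zinc finger gene ZNF704 at 1.49 ± 0.19 and the secreted hormone STC2 at 1.37 ± 0.22. MUC1 (1.11 ± 0.14) and PHGDH (0.90 ± 0.13) rose and BNIP3 (-0.73 ± 0.14) fell among list members. In all 219 of 12515 genes passed, 85 higher and 134 lower. The count was 0 when any of 6 of the 8 stimulated arrays was left out and 0 without the intensity trend, and 297 without the A549 array labelled unstimulated control. Other bright probe sets were weaker for AXL (-0.06), REEP5 (-0.30) and SLC2A3 (0.70 and 0.92).

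A candidate list came from work on nicotine, EGF and ID1 in lung cancer lines that can include these samples, so its direction is not independent evidence. Of its 6 members GSPT1, a translation termination factor, fell by 1.41 ± 0.20, and adjusted over the list alone 2 fell. GSPT1 fell in both lines, by 1.67 ± 0.11 in A549 and 1.14 ± 0.11 in H1650, with another of its bright probe sets at 0.29 in the mean. STMN3, a microtubule-destabilising stathmin, fell by 0.77 ± 0.22 in A549 and was -0.28 ± 0.22 in H1650 without passing. The kinase TBK1 fell in both, by 0.39 ± 0.11 and 0.42 ± 0.11, and VIM, FN1 and ZNF148 passed in neither line. Vimentin (VIM) was -0.36 ± 0.14 and -0.06 ± 0.14, fibronectin (FN1) 0.18 ± 0.11 and -0.20 ± 0.11. Within A549 3 candidates fell, 4 adjusted over the list alone, and within H1650 2 by either count.

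Over both lines camera called the candidates lower (median -0.31, adjusted p = 0.0258) and NF-kB (0.73, 0.00491), interferon (1.24, 0.00573), mesenchymal (0.64, 0.0274) and stress genes (0.19, 0.0258) higher, with oxidative phosphorylation lower (-0.14, 0.0325). Each had adjusted p = 0.973 with an estimated correlation, and under quantile normalization the candidates stood at 0.0693 and oxidative phosphorylation at 0.535. The interferon and NF-kB medians here average opposite signs in the lines (NF-kB 1.54 in A549 and -0.22 in H1650), the mesenchymal one 0.82 and 0.07, and 0 of 25 interferon genes passed limma. Adjusted over the list alone, 7 stress and 3 NF-kB genes rose. Genes changed at least 2-fold in both pairs of a line were 482 higher and 70 lower in A549, where independent pairs would give 60.3 and 3.23, and 60 higher and 92 lower in H1650, against 4.78 and 6.54. In both lines 16 were higher, among them IGFBP3, which binds insulin-like growth factors, MMP3 and AOX1, an aldehyde oxidase, and 16 were lower, including AXL, the RNA-binding protein PCBP1, TSPAN13 and GPD2; independent lists would share 2.31 and 0.515. A further 15 were higher in A549 and lower in H1650, MX1 and MMP1 among them, against 3.54, and 0 the opposite way against 0.336.

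Under nicotine alone, AXL (-1.59 ± 0.17) and VSTM2L (3.53 ± 0.39, at least 2.16-fold) had the smallest limma adjusted p, 0.0807. GALNT7 was -1.83 ± 0.31, REEP5 -1.65 ± 0.31 and the secreted BMP antagonist GREM1 2.37 ± 0.57. Under EGF, REEP5 was -1.68 ± 0.31, VAMP3 -1.67 ± 0.34, the small GTPase ARF3 -1.37 ± 0.25, CCL2 1.89 ± 0.47 and AOX1 2.24 ± 0.75. For EGF minus nicotine, SFTPC, surfactant protein C, was 2.04 ± 0.41. Limma called 0 genes in these 3 comparisons, with 1385, 1611 and 126 genes at an unadjusted p under 0.05 where chance gives 626. Camera called NF-kB (medians 0.51 under nicotine and 0.95 under EGF, adjusted p = 0.0258 and 0.00389) and interferon genes (1.28 and 1.23, 0.00776 and 0.0258) higher and the candidates lower (0.0382 and 0.0274) in both. By line, interferon medians were 3.36 and 2.94 in A549 and -1.07 and -0.65 in H1650, and NF-kB medians 1.44 and 1.80 in A549 and -0.43 and 0.07 in H1650. Stress genes were higher under nicotine (0.25, 0.00765), and mesenchymal markers were higher (0.72, 0.0305) and ribosomal (-0.20, 0.0305) and oxidative phosphorylation genes (-0.20, 0.00994) lower under EGF. ERK response genes were lower in the difference (-0.13, 0.0228). Every one of these had adjusted p = 0.973 with an estimated correlation, and quantile normalization ended the candidate, ribosomal, oxidative phosphorylation and ERK calls.

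In both A549 pairs more genes were at least 2-fold higher than lower with ID1 siRNA. There, 758 genes were at least 2-fold higher and 205 lower in A549 under nicotine, and 996 and 197 under EGF. The H1650 numbers were 229 and 337 under nicotine and 261 and 243 under EGF. After each array was centred on its median the A549 numbers were 497 and 497 under nicotine and 611 and 703 under EGF, and the H1650 numbers 228 and 340 under nicotine and 197 and 339 under EGF. Against no stimulus, 207 genes were higher and 430 lower with nicotine in A549, 205 and 640 with EGF, and in H1650 130 and 72 with nicotine and 169 and 261 with EGF. Centred, these were 219 and 414, 275 and 526, 98 and 99, and 168 and 265.

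Nicotine and EGF were compared with no stimulus under control siRNA, and no single gene passed. RASD1, a Ras-like GTPase induced by glucocorticoids, was higher with nicotine (2.12 ± 0.35) and with EGF (1.92 ± 0.35), both against the same unstimulated arrays. With nicotine GREM1 was -1.88 ± 0.57, and VSTM2L -2.85 ± 0.39, at least 1.34-fold lower. With EGF SPOCD1 was 2.11 ± 0.50, ALDH3A1 1.27 ± 0.34, the chemokine CXCL6 -2.48 ± 0.74, the amino acid transporter subunit SLC7A7 -2.17 ± 0.39 and the stress-induced NUPR1 -1.80 ± 0.40. Limma called 0 genes for either stimulus. At an unadjusted p under 0.05 there were 189 genes for nicotine and 747 for EGF, where chance gives 626. The error pools how far the lines disagreed over all 5 conditions, the ID1 siRNA arrays included. It may be too large for these contrasts, so 0 calls cannot show that few genes changed in both lines. ERK response genes were higher with EGF as a list (median 0.32, camera adjusted p = 8.51e-05), with 0 of 19 passing, 1 adjusted over the list alone, and examples EGR1 (1.32 ± 0.67), FOS (1.02 ± 0.63) and PHLDA1 (0.72 ± 0.15). With an estimated correlation this list had camera adjusted p = 0.973 and was not called.

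Directions in A549 rest on the array labelled unstimulated control. Mesenchymal markers (medians -0.45 with nicotine and -0.59 with EGF), p53 targets (-0.36 and -0.44) and NF-kB genes (-0.25 and -0.61) were lower with both stimuli, and interferon (-0.60), protease (-0.25) and stress genes (-0.23) lower with nicotine. Ribosomal (0.31) and tubulin genes (0.26) were higher with EGF, but quantile normalization brought the ribosomal median to 0.00 and ended both calls. It also ended the interferon and protease calls for nicotine. With the A549 array labelled unstimulated control left out, the mesenchymal and p53 calls ended for both stimuli and the protease and stress calls for nicotine. NF-kB genes stayed called by camera (adjusted p = 0.0438 with nicotine and 0.035 with EGF). The interferon median with nicotine then went to -1.39 (camera adjusted p = 1.72e-07), which the H1650 pair below does not bear out. A549 entered these contrasts through the line term alone, so calls lost or gained cannot show what that array did. With all arrays kept, camera adjusted p lay between 4.26e-05 and 0.0382 for the lists of this paragraph, and was 0.973 for each with an estimated correlation. In the H1650 pairs, which do not use that array, mesenchymal medians were 0.05 and 0.10, NF-kB medians 0.11 and -0.33, and the interferon median with nicotine 0.02, so for these 3 lists the lower values with nicotine come from A549, while the stress median with nicotine was -0.09. In the A549 pairs p53 targets had medians of -0.71 and -0.91, below all random lists of like intensity, and in the H1650 pairs 0.00 and -0.03, at percentiles 64.3 and 40.7. In H1650 with EGF alone, ERK response genes had a median of 0.34, above all random lists, with 18 of 19 higher. Interferon genes had a median of -0.88 there, with 1 of 25 higher, and of -0.42 in the A549 EGF pair, with 7 of 25 higher. Both medians lay below all random lists, and the A549 one uses the array labelled unstimulated control. In the A549 EGF pair the ERK median was 0.10, at percentile 85.4, with 14 of 19 higher.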

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

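The limma contrast between lines was set before the data were examined, and the tests of explanations in this part were chosen after the results had been seen. For 1490 genes the ID1 siRNA effect differed between A549 and H1650, 874 of them higher in A549, though after array-median centring the split was 624 higher and 1821 lower. The difference held for 24 interferon genes and 12 NF-kB and inflammatory genes with a higher effect in A549, 20 G2/M genes with a lower effect and 10 p53 targets with a higher effect.

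The interferon genes moved in opposite directions, with medians of 3.03 in A549 and -0.87 in H1650. Exchanged siRNA labels in 1 line would raise ID1 on the arrays labelled ID1 siRNA, but the smallest change was a log2 of -1.183, so this was excluded. Array scaling was excluded as well, since the median difference was 3.661 under quantile normalization. Interferon levels of the controls were unlike, at a mean log2 signal of 8.33 and 9.09 in A549 and 12.18 and 11.23 in H1650, which may set how far each line could move. A response to the transfected siRNA itself could not be told from an effect of ID1 loss, because the labels name no second ID1 siRNA and give no sequence.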

How the results depend on the processing

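The alternatives were planned before the data were examined, except for 3 chosen after the results had been seen. Lists within lines gave 33 calls. Lists without the A549 array labelled unstimulated control gave 29 calls. Some of these were new ones that the H1650 pairs do not bear out, since A549 then enters the stimulus contrasts through the line term. Genes 2-fold changed without the A549 control EGF array numbered 837 against 704. There the A549 nicotine control stood in for the missing array, so both A549 comparisons shared a control. A shared control by itself makes the comparisons alike, so the higher count is not evidence that the result is robust. Where no cause is given, the cause was not tested. Of 2793 values of 156 gene results named above, over 20 settings, 301 no longer passed and 11 passed only then. Of the former, 62 came without the intensity trend. A reversal was counted only where the gene passed in the main or the alternative setting, and there were 0. Sign changes of results that passed in neither were not counted.

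The mean ID1 siRNA effect had 219 calls. The count was 711 after centring (85 higher, 626 lower, against 85 and 134), 88 without a filter, 357 with a filter at the 75th percentile, 341 with a filter on the highest array, 7 with the mean of probe sets (among them AXL and IGFBP3), 469 with the matched pair as block and 989 at an adjusted p under 0.1. It was 0 without the intensity trend (2529 at an unadjusted p under 0.05) and 0 without the line as block (487). Leaving out 1 array gave 0 to 450: 0 without either A549 ID1 siRNA array, either stimulated A549 control or either H1650 ID1 siRNA array, 4 without the H1650 nicotine control and 450 without the H1650 EGF control.

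Under nicotine limma called 0 genes, 1 without the intensity trend, and 0 to 4 with 1 array left out: 4 without the unstimulated H1650 control, 3 without the A549 array labelled so and 2 without the H1650 nicotine control. Under EGF it was 0 to 1, with 1 call, not named here, without the A549 ID1 siRNA EGF array. EGF minus nicotine, nicotine and EGF stayed at 0.

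Between A549 and H1650 the 7894 calls stayed within 7029 to 7453 when 1 array was left out, and centring gave 4576 higher and 3189 lower against 3863 and 4031. The difference in ID1 siRNA effect, 1490 calls, was 2445 after centring (624 higher, 1821 lower, against 874 and 616), 636 with the mean of probe sets, 199 without the trend (179 higher), and 878 to 1666 with 1 array left out, 878 without the A549 ID1 siRNA EGF array and 885 without the A549 EGF control. Within A549, 3161 calls became 4916 after centring (948 higher, 3968 lower, against 1733 and 1428), 1747 with the mean of probe sets, 1394 without the trend and 1452 to 3601 with 1 array left out, 1452 without the EGF control and 1456 without the ID1 siRNA EGF array. Within H1650, 1540 calls became 592 with the mean of probe sets, 1 without the trend and 981 to 1862, 981 without the nicotine control and 1003 without the ID1 siRNA nicotine array, and centring gave 617 higher and 1127 lower against 706 and 834.

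Genes 2-fold changed in both pairs of a line, 704, numbered 2381 without a filter, 343 with the 75th percentile and 2443 at 1.5-fold. Single pairs summed to 5340, 29064 without a filter, 1588 at the 75th percentile, 3200 with the highest array and 17007 at 1.5-fold. These differences follow from how many genes, or how small a change, each alternative admits. Camera called 33 combinations of list and contrast over all arrays, 0 with an estimated correlation, and fry called 10. The dimmer probe sets limit these arrays: signals near 66.7 lie at the median of all probe sets.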

Other observations

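The tests in this part were chosen after the results had been seen, apart from regrouping the arrays, which was planned before the data were examined. The 8 stimulated arrays were regrouped in a fit of all 10 arrays with line and stimulus as blocks. It gave 754 calls for the real grouping and at most 1 in any other of the 34 groupings run out of 35 possible. The terms differ from those of the fit with 219 calls. Only 8 groupings, the real one included, part all 4 matched pairs. Of 100 groupings run for the lines, out of 126, again 1 reached the real 7894, and the highest other gave 73. Other groupings leave the real siRNA or line difference in the residual spread. That alone keeps their calls few, so these counts cannot decide how often unrelated arrays would give as many.

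The A549 array labelled unstimulated control lay on the side of the ID1 siRNA arrays. Of 92 genes at least 2-fold lower in both H1650 pairs, 69 were lower there than in the stimulated A549 controls, with a median of -0.50 against -0.38 on the A549 ID1 siRNA arrays. The ratio of these medians was 1.332, and for 60 genes higher in both H1650 pairs it was 0.768. These values may reflect a sample that received ID1 siRNA without a stimulus, but stimuli that change ID1 and its genes in A549 alone would give the same, and these could not be told apart. The correlation across genes with the H1650 effect was 0.235 in the main setting and 0.2406 under quantile normalization. A constant added to a whole array cannot change a correlation across genes. These values therefore do not decide whether scaling shifted the medians above. An exchange with a stimulated ID1 siRNA sample could not be excluded. On that array interferon genes stood at a median of 0.87 above the controls, against 2.68 and 3.37 on the ID1 siRNA arrays. The ratio was 0.289. The array thus differed from both in these genes, but after an exchange 1 of them would itself be the unstimulated control.

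Of A549 genes 2-fold changed in both pairs, 87.3% were higher with ID1 siRNA. After each array was centred on its median the share was 59.41%, but centring itself pulls the counts together, so this decides nothing about a shift of the whole array. In H1650 39.47% were higher, but its spikes were brightened less than those of A549, which leaves brighter hybridisation open too, with bioB and bioC brighter in A549 and cre not (0.994-fold and 0.785-fold). Whether so many transcripts truly rose was not tested, and no control of known amount per cell was available.

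Across genes, the EGF effect and the ID1 siRNA effect under nicotine, which share no array, correlated at r = -0.446 in A549 and 0.058 in H1650. The NF-kB genes in H1650 had medians of 0.11 with nicotine and -0.33 with EGF, at percentiles 99.97 and 0 of random lists, and nicotinic receptor subunits in A549 had -0.16 and -0.54, at percentiles 22.2 and 5.16. Other probe sets above the signal filter, dimmer than the one used for the tests, were compared with it in each contrast that named their gene. Of 63 such comparisons 8 went the opposite way, in 5 genes, and a probe set can be counted in several contrasts.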
